A study of Spinacia oleracea with 6 samples.

How the data were processed

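RNA sequencing libraries of spinach, Spinacia oleracea, were compared between 2 temperature regimes. The samples came from plants kept in an illumination incubator, and total RNA was isolated with TRIZOL before standard Illumina library preparation, per the labels' protocols. Control samples were held at 20 °C by day and 15 °C by night, and heat samples at 35 °C by day and 25 °C by night, for 4 days. Each regime had 3 libraries, and the groups and replicate numbers were taken from the labels. The labels do not name the tissue. Nothing in the labels says that the libraries of a group came from separate plants or pots, so p-values measure only the spread between these samples, which may be technical.

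The deposited tables hold 1 value per gene and library for 32450 genes. The first table gives read counts per gene that the authors made without normalization, as whole numbers that sum to between 42.3 and 56.8 M per library. The second gives FPKM values computed by the authors, and every value of 20305 genes checked equalled the deposited count divided by a fixed length per gene and by the library's total count, within a relative tolerance of 1e-06. The length of each gene in base pairs was recovered from that relation. A further deposited file holds exons of 1718 gene models that the authors added to the annotation, with 3442 transcript models on 1130 scaffolds. How these models were made is not given in the sources used here. HISAT2 2.0.4, HTSeq 0.9.1 and DESeq 1.18.0 are listed per the submitters' processing notes, without the role or order of each. The genome build, the annotation, the treatment of reads that align to several places and the use of strand are not given in the sources used here. Reads of near-identical gene copies or of overlapping genes could therefore have been split or dropped, and whether reads of antisense pairs were separated is unknown.

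Apart from the added models, the tables identify genes by 30732 NCBI Gene numbers. Of these, 25304 (82.3%) matched a reference gene table of the BTI_SOV_V1 assembly by gene number, which gave a symbol and a gene class for each. The remaining numbers are called unmatched genes here. Most symbols were locus numbers without a name, and 0 gene descriptions were found. For 135 protein-coding genes the table also gave a gene name, as a symbol or as a synonym, and 125 of them were tested.

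Differential expression was tested on the counts with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3). TMM scaling, edgeR's own filter on low counts and a model with group as its only term were used, and all 6 libraries entered the fit. The tests were two-sided, with Benjamini-Hochberg adjustment over the 20145 genes that passed the filter and a threshold of 0.05. Log2 fold changes are heat minus control, and SE is their standard error. Levels are given as CPM, counts scaled to a common library size, on the TMM scale, with the SD over the 3 libraries of a group. In the count table, 1 read corresponded to between 0.0176 and 0.0236 CPM of a library's total, and a gene at 0 was given an upper limit of 3 counts. Limits and counting intervals, at the 95% level, cover counting error only. Measures of whole libraries were compared by an exact two-sided permutation test, which with 3 libraries against 3 cannot give a p below 0.1. Odds ratios across genes were tested with Fisher's exact test, and genes are not independent replicates.

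The test, the model, the thresholds, the rule for named genes and the main list of alternatives were chosen before the data were examined. Under that rule, because no descriptions were found, the genes with the largest rise and the largest fall were named, at most 2 of each, among genes past the threshold with a mean of at least 10 CPM and no overlap between the groups. The same was done for the added models. The 34 gene lists prepared by description patterns were not tested as written, because they need descriptions. Gene groups were built in their place from the synonyms in the reference table, after the data had been examined, so plastid-encoded genes, which the table gives by symbol, entered no group at first. Of the 125 tested genes with names, 72 were placed in 16 groups, 13 of which keep the title of a prepared list and 3 of which were added. The 10 groups with at least 3 tested members were tested with limma's camera on voom log2 CPM (limma 3.58.1), with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 10 groups. For each group, the examples were the 2 members past the threshold with the largest change and a mean of at least 10 CPM, or the most abundant member where fewer passed. Genes given by reference name were thus chosen after their values were seen, and what each encodes was taken from general knowledge of its name alone, with no sequence compared. Small heat shock proteins, HSP90 and heat stress transcription factors had no member among these names and were not analysed here. Of the HSP70 chaperones, only the 3 genes placed by name were analysed.

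Before use, the procedure was tested on simulated counts drawn from the means and dispersions of the 6 libraries. For the comparison of heat with control on 19869 genes, edgeR recovered 1.49% of 67 genes changed 1.5-fold, 13.4% of 67 genes changed 2-fold and 60.6% of 66 genes changed 4-fold, with 3 unchanged genes called (5.66% of its calls). In the same simulation DESeq2, which fitted 20145 genes, called 65 unchanged genes (40.9% of its calls) and limma-voom 3 (6.38%). Far fewer genes were changed there than were called in the data. Neither the recovered nor the false shares therefore carry over to the real comparison. In a further simulation on 20145 genes, camera called a set of 12 genes lowered 2-fold (adjusted p = 6.84e-18) and 0 of 20 unchanged sets. Its genes were drawn independently of each other, so it does not show how camera behaves where genes are correlated. Alternatives were other scalings (DESeq2's size factors, upper quartile, library size alone), other filters on low counts, DESeq2 1.42.0, limma-voom and a model with the replicate number as a block. Further ones were limma on log2(FPKM + 1) with and without a minimum mean FPKM of 1 and on log2(FPKM + 0.1) with it, a scale that understates the change of low genes, stricter thresholds and the omission of each library in turn. Tables were handled with pandas 2.3.3 and figures drawn with matplotlib 3.10.9 in Python 3.11.15.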

Results

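Gene expression was measured by RNA sequencing in 6 spinach libraries, 3 from plants kept at 20 °C by day and 15 °C by night (control) and 3 from plants kept at 35 °C by day and 25 °C by night (heat) for 4 days. The stated purpose was to find genes whose expression differs under heat, including genes that could be associated with resilience. Total counts were 53.5, 56.8 and 48.4 M in control libraries 1 to 3 and 48.0, 44.0 and 42.3 M in heat libraries 1 to 3.

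The control libraries were deeper than the heat libraries, at 52.9 ± 4.24 against 44.8 ± 2.92 M counts (mean ± SD, n = 3 each; exact permutation p = 0.1, the smallest the design allows). Reads were detected for 22395 ± 277 genes in control and 22702 ± 114 in heat. The 10 most abundant genes of each library took 14.1% ± 1.93 of the counts in control and 8.63% ± 0.864 in heat. Counts were thus more concentrated in a few genes in every control library than in any heat library, and this difference also had an exact permutation p of 0.1. Over the 8 library measures compared, the adjusted p was 0.114 for every measure but the share of counts in matched plastid-encoded genes, at 0.9. Pearson correlations of log2 CPM, computed across genes that are not independent, were 0.930 to 0.961 within control, 0.942 to 0.961 within heat and 0.865 to 0.899 between the groups. On the plot of libraries, the first principal component, with 59.9% of the variance, separated the groups, and no 2 libraries of a group agreed within sampling noise.

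**Figure D1:**
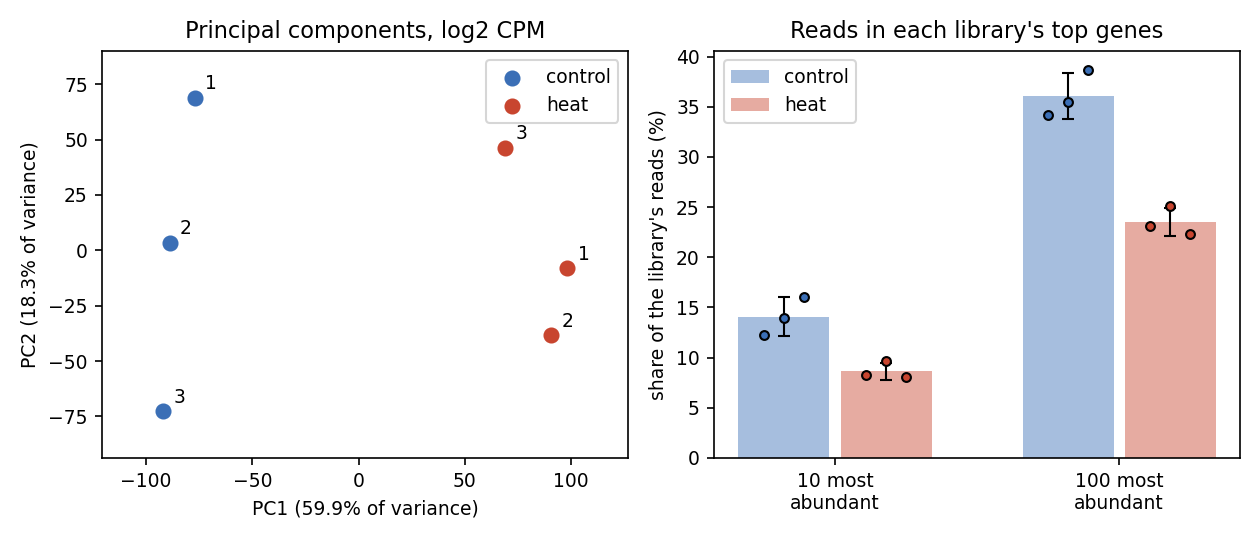
Principal component scores and the shares of reads in the 10 and the 100 most abundant genes of each library are plotted, with each point 1 library and bars at group means with SD. The control libraries lie apart from the heat libraries on the first component, which holds 59.9% of the variance.

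In the comparison of heat with control, the nuclear genes that were grouped by their names in the BTI_SOV_V1 gene table as photosynthetic apparatus were lower in heat, while the 2 plastid-encoded ones tested, petB and atpF, did not pass. petB and atpF had at most 214 and 27 reads in a library. Their log2 fold changes were -1.08 (-0.007 without control library 3) and -1.77, so a response unlike that of the nuclear genes is not shown. All 12 tested subunits of photosystems I and II fell, with log2 fold changes from -2.22 to -1.16. For psaL (LOC110791435), a subunit of photosystem I, the level went from 1973 ± 124 CPM in control to 477 ± 38.3 CPM in heat (n = 3 each; log2 fold change -2.05, SE 0.18, adjusted p = 0.000741). psbS (LOC110795972), which is required for the dissipation of excess light energy at photosystem II, went from 94.3 ± 16.3 to 20.2 ± 7.92 CPM (log2 fold change -2.22, SE 0.30, adjusted p = 0.00332). lhcb1.3 (LOC110802314), a light-harvesting chlorophyll-binding protein, went from 6338 ± 1280 to 664 ± 183 CPM (log2 fold change -3.26, SE 0.30, adjusted p = 0.000871).

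Nuclear genes of carbon fixation and electron transport fell as well. All 8 tested genes placed in the Calvin-Benson cycle were lower in heat, with log2 fold changes from -3.69 to -1.85. rbcS2 (LOC110780027), which encodes the small subunit of the carbon-fixing enzyme Rubisco, decreased from 2905 ± 518 to 224 ± 61.9 CPM (log2 fold change -3.69, SE 0.29, adjusted p = 0.000563), and gapA (LOC110805429), a chloroplast glyceraldehyde phosphate dehydrogenase, from 1170 ± 228 to 95.1 ± 23.1 CPM (log2 fold change -3.62, SE 0.27, adjusted p = 0.000485). Among electron carriers and subunits of the chloroplast ATP synthase, 6 of 8 tested genes fell, all of them nuclear, and petB (adjusted p = 0.260) and atpF (adjusted p = 0.119) did not pass. PETE (LOC110799213), plastocyanin, dropped from 951 ± 71.2 to 154 ± 22 CPM (log2 fold change -2.62, SE 0.19, adjusted p = 0.000448) and ATPG (LOC110788390), of the ATP synthase, from 561 ± 70.3 to 114 ± 34.6 CPM (log2 fold change -2.30, SE 0.26, adjusted p = 0.00161). GOX (LOC110805661), glycolate oxidase of photorespiration, went from 10128 ± 1661 to 2394 ± 355 CPM (log2 fold change -2.08, SE 0.26, adjusted p = 0.00229), a call lost with limma on log2(FPKM + 1) without a filter (adjusted p = 0.0579).

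Against all other genes, camera placed the photosystem group (adjusted p = 1.18e-09), the Calvin-Benson group (adjusted p = 1.29e-09) and the electron carrier group of 6 nuclear genes (adjusted p = 5.76e-06) lower in heat. With an estimated correlation between the genes, the Calvin-Benson group (adjusted p = 0.0282) and the electron carrier group (adjusted p = 0.0401) stayed past the threshold. The photosystem group did not (adjusted p = 0.127 with an estimated correlation). The estimate was 0.36 for the photosystem group, -0.0009 for the Calvin-Benson group and -0.042 for the electron carrier group. Adjusted p thus rose even where the estimate lay below the preset 0.01, so correlation between genes is not the only source of the rise. With petB and atpF added after the results were seen, the electron carrier group had an adjusted p of 1.49e-05 and, with an estimated correlation, no longer passed (adjusted p = 0.0577 with an estimated correlation). Adjusted over the list alone, 12, 8 and 6 genes were lower, and under library size alone all members of these groups still fell. Of 10000 random lists matched on mean CPM, 3.11% had a median as low as the photosystem group, 3.2% as the electron carrier group (0.97% with petB and atpF) and 0.02% as the Calvin-Benson group.

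Genes of nitrogen assimilation and of glycine betaine synthesis also decreased. In nitrogen assimilation all 3 tested genes fell, among them NIA (LOC110786500), nitrate reductase, from 2158 ± 659 to 112 ± 87.1 CPM (log2 fold change -4.26, SE 0.60, adjusted p = 0.00363) and Fd-GOGAT (LOC110777056), glutamate synthase, from 2146 ± 404 to 538 ± 105 CPM (log2 fold change -2.0, SE 0.24, adjusted p = 0.00223). Glycine betaine is a solute that spinach accumulates under stress, and all 3 tested genes of its synthesis fell. PEAMT (LOC110779155), a methyltransferase on the way to choline, went from 454 ± 137 to 34.0 ± 25.3 CPM (log2 fold change -3.74, SE 0.56, adjusted p = 0.00460) and BADH (LOC110776905), betaine aldehyde dehydrogenase, from 517 ± 32.6 to 87.6 ± 41.6 CPM (log2 fold change -2.56, SE 0.35, adjusted p = 0.00317). camera gave an adjusted p of 0.00158 for nitrogen assimilation and 0.00191 for glycine betaine synthesis, and neither passed with an estimated correlation (adjusted p = 0.173 and adjusted p = 0.164). In both groups all 3 genes were also lower when adjusted over the list alone. Of random lists matched on mean CPM, 10.9% had a median as low as the nitrogen assimilation genes and 1.35% as the glycine betaine genes. Heat library 3 had the highest level of NIA and PEAMT in heat, and without it their log2 fold changes were -5.12 and -4.55.

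Of the 3 tested HSP70 chaperones with names, proteins that assist folding, 2 were lower in heat. Other HSP70 genes, any induced by heat among them, were not identified here, so the direction of the family is not shown. HSC70-1 (LOC110792092) decreased from 1700 ± 182 to 421 ± 69.9 CPM (log2 fold change -2.01, SE 0.21, adjusted p = 0.00121) and HSC70-9 (LOC110785563) from 1272 ± 315 to 352 ± 47.5 CPM (log2 fold change -1.85, SE 0.25, adjusted p = 0.00297). BiP (LOC110783146), the chaperone of the endoplasmic reticulum, stood at 37.5 ± 7.60 CPM in control and 26.9 ± 8.85 CPM in heat (log2 fold change -0.48, adjusted p = 0.251). The group had an adjusted p of 0.00888 with camera and 0.187 with an estimated correlation, 2 members were lower adjusted over the list alone, and 3.31% of lists matched on mean CPM had a median as low. The chaperonin cofactor CPN21 (LOC110784547) fell from 51.9 ± 7.16 to 29.8 ± 3.08 CPM (log2 fold change -0.80, SE 0.16, adjusted p = 0.0120), a call that ended without heat library 1 (adjusted p = 0.0545) and when libraries were scaled by size alone (log2 fold change -0.34, adjusted p = 0.213).

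Of 19 tested genes placed among plastid ribosomal proteins, 5 fell and 14 did not pass, and 6 were lower adjusted over the list alone. DESeq2 called 7 lower and limma-voom 5, while library size alone and limma on log2(FPKM + 1) called 2 each, and 10 had an unadjusted p below 0.05 with edgeR. CL35 (LOC110791005) went from 75.4 ± 15.5 to 14.3 ± 0.422 CPM (log2 fold change -2.40, SE 0.18, adjusted p = 0.000498) and CL13 (LOC110782699) from 109 ± 27.2 to 32 ± 3.91 CPM (log2 fold change -1.77, SE 0.21, adjusted p = 0.00204). The median of the group was -0.44 and became 0.02 under library size alone, and its adjusted p of 0.00158 with camera became 0.0531 under library size alone and 0.364 with an estimated correlation. Among antioxidant enzymes, 0 of 4 tested genes passed edgeR's quasi-likelihood test and 0 had an unadjusted p below 0.05. DESeq2 and limma-voom also called 0 of them, while limma on log2(FPKM + 1), whose values are scaled by library totals alone, called 2 higher. The most abundant of them, PHGPx (LOC110778554), a glutathione peroxidase, had 252 ± 99.7 CPM in control and 325 ± 112 CPM in heat (log2 fold change 0.36, SE 0.34, adjusted p = 0.473). Of the proteasome subunits, 0 of 3 passed with edgeR, DESeq2 or limma-voom, 0 had an unadjusted p below 0.05, and 2 were called higher under library size alone and on log2(FPKM + 1). RPT1 (LOC110787189), of the regulatory particle, had 177 ± 28.7 CPM in control and 219 ± 44.6 CPM in heat (log2 fold change 0.31, SE 0.21, adjusted p = 0.318). camera gave both groups an adjusted p of 0.870 and, with an estimated correlation, 0.901.

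Both tested fatty acid desaturases fell, fad6 (LOC110799552) from 422 ± 36.8 to 210 ± 28.7 CPM (log2 fold change -1.0, SE 0.17, adjusted p = 0.00702) and sadA (LOC110785399) from 60.4 ± 0.185 to 31.9 ± 4.00 CPM (log2 fold change -0.92, SE 0.14, adjusted p = 0.00468). SPS (LOC110801165), sucrose-phosphate synthase, decreased from 251 ± 45.9 to 142 ± 21.7 CPM (log2 fold change -0.82, SE 0.20, adjusted p = 0.0246). The SPS call was lost without control library 2 or 3 or heat library 2 or 3 (adjusted p from 0.0621 to 0.101). Scaling by library size alone ended the calls of fad6 (log2 fold change -0.54, adjusted p = 0.0666) and SPS (log2 fold change -0.35, adjusted p = 0.142). HEMB (LOC110796930), of tetrapyrrole synthesis, had 136 ± 13.9 CPM in control and 101 ± 20.9 CPM in heat (adjusted p = 0.143), with a log2 fold change of -0.43 that became 0.03 under library size alone.

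Of all 125 tested genes with a reference name, 73 were lower, 49 did not pass and 3 were higher, and under library size alone 56 were lower and 7 higher. prs2 (LOC110792433), phosphoribosyl diphosphate synthase of nucleotide synthesis, rose 18.2-fold, from 46.0 ± 16.9 to 837 ± 174 CPM (log2 fold change 4.19, SE 0.34, adjusted p = 0.000635). s1Fa (LOC110779082), a small DNA-binding protein, rose from 68.2 ± 9.59 to 155 ± 22.7 CPM (log2 fold change 1.2, SE 0.18, adjusted p = 0.00460). The ferredoxin-thioredoxin system, which passes electrons from photosystem I to regulated chloroplast enzymes, had members in both directions. FTRV (LOC110781961), the variable chain of ferredoxin-thioredoxin reductase, rose from 66.7 ± 0.974 to 101 ± 11.9 CPM (log2 fold change 0.60, SE 0.14, adjusted p = 0.0216), while FTRC (LOC110802350), its catalytic chain, fell from 77.9 ± 12.3 to 23.7 ± 2.04 CPM (log2 fold change -1.72, SE 0.16, adjusted p = 0.000964). Trx-M (LOC110782047), a thioredoxin, fell from 428 ± 35.5 to 120 ± 20.2 CPM (log2 fold change -1.84, SE 0.18, adjusted p = 0.00112). The fourth member, B1 (LOC110798481), had a log2 fold change of -0.67 (adjusted p = 0.119, or 0.0453 over the list alone, where 3 members were lower and 1 higher), and the group had an adjusted p of 0.0758 with camera and 0.364 with an estimated correlation. The FTRV call was lost without control library 1, 2 or 3 or heat library 1 (adjusted p from 0.0511 to 0.0995).

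Compared with other protein-coding genes, the odds of a gene with a reference name being lower were 7.72 times as high (95% interval 5.32 to 11.3; Fisher's exact test across genes, p = 9.19e-28). These genes had been named in earlier work and are no random sample of the genome, with a median of 184 CPM. Group membership was set after the data had been examined, so the group tests describe these libraries and are not independent evidence of a direction.

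**Figure D2:**
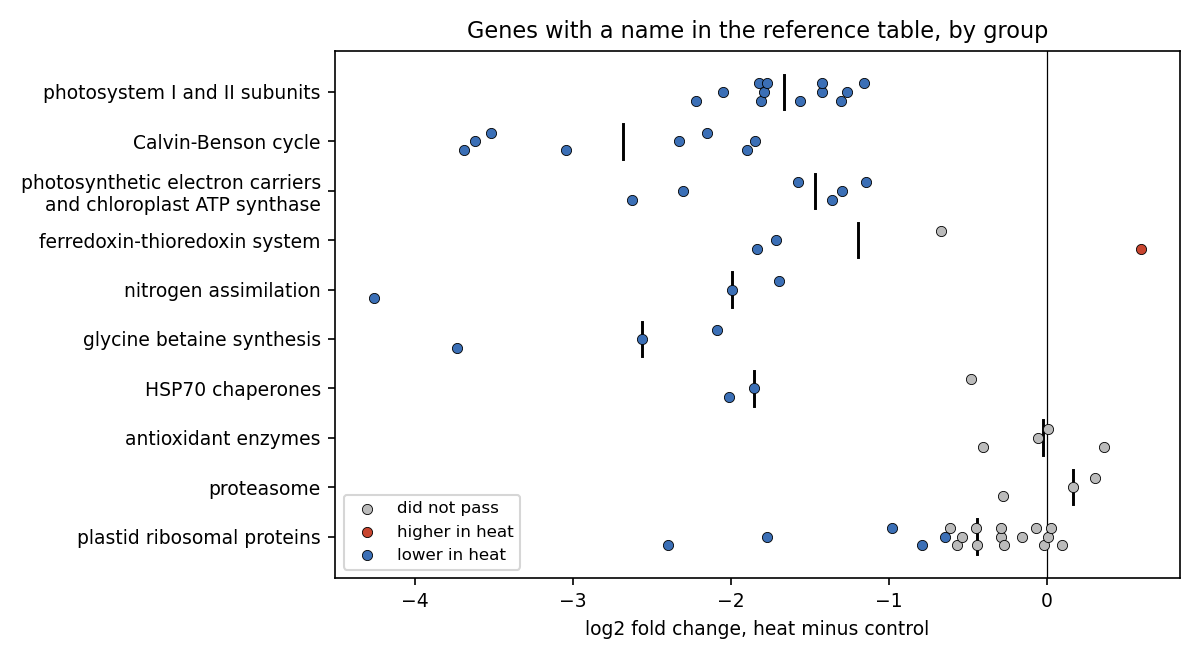
Log2 fold changes (heat minus control) of the tested members of each gene group are plotted, with each point 1 gene. All 12 photosystem subunits and all 8 Calvin-Benson genes lie below 0, while the antioxidant genes lie between -0.40 and 0.36 and the proteasome genes between -0.28 and 0.31 under TMM scaling.

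Over the whole transcriptome, 5074 of 20145 tested genes (25.2%) differed between heat and control at an adjusted p below 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 2339 (46.1%) were higher and 2735 (53.9%) lower in heat. At least 2-fold changes were found for 3383 genes, 1447 higher and 1936 lower. Changes of at least 4-fold were found for 682 higher and 789 lower genes, and of at least 16-fold for 193 and 128. The groups did not overlap for 9101 tested genes (45.2%), where chance gives 10%. The split by direction depended on the scaling. Under library size alone, 7759 genes passed and 6288 of them (81.0%) were higher, as the median log2 fold change of all tested genes moved from 0.01 to 0.47. Without control library 2 the count was 2291 (864 higher, 1427 lower), of which 2064 changed at least 2-fold, and without heat library 1 it was 2651 (1109 higher, 1542 lower), of which 2211 did.

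Some genes were detected in a single regime. At 0 reads in every control library and at least 10 in every heat library were 24 genes, and the reverse held for 6. The greatest rise by the fixed rule was that of LOC110790088, with 0 reads in all control libraries and 37.6 ± 33.8 CPM in heat (adjusted p = 0.0149). Set against a floor of 3 counts over the control group, its mean was at least 1703-fold higher and its lowest heat library at least 119-fold higher. Without heat library 2 the first limit was 967-fold, without heat library 3 the limits were 2495-fold and 1816-fold, and without control library 1 or 2, where fewer reads set the floor, 1089-fold and 76-fold or 1086-fold and 76-fold. LOC110790088 had 2228, 3442 and 140 reads in the heat libraries, and its call was lost without heat library 1 (adjusted p = 0.0512) and with limma-voom (adjusted p = 0.161). LOC110797217 rose 306-fold, from 0.674 ± 0.470 to 207 ± 41.7 CPM (log2 fold change 8.23, SE 0.54, adjusted p = 0.000382; 8.94 without control library 2). The greatest fall was that of LOC110782908, from 289 ± 167 to 0.0326 ± 0.0247 CPM (log2 fold change -13.04, SE 0.87, adjusted p = 0.000382; -13.75 without heat library 2), with 5 reads over the heat libraries. LOC110776184 fell from 49.5 ± 25.4 to 0.172 ± 0.207 CPM (log2 fold change -8.19, SE 0.87, adjusted p = 0.00140; -9.74 without heat library 2). The reference table gave no name for these genes.

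**Figure D3:**
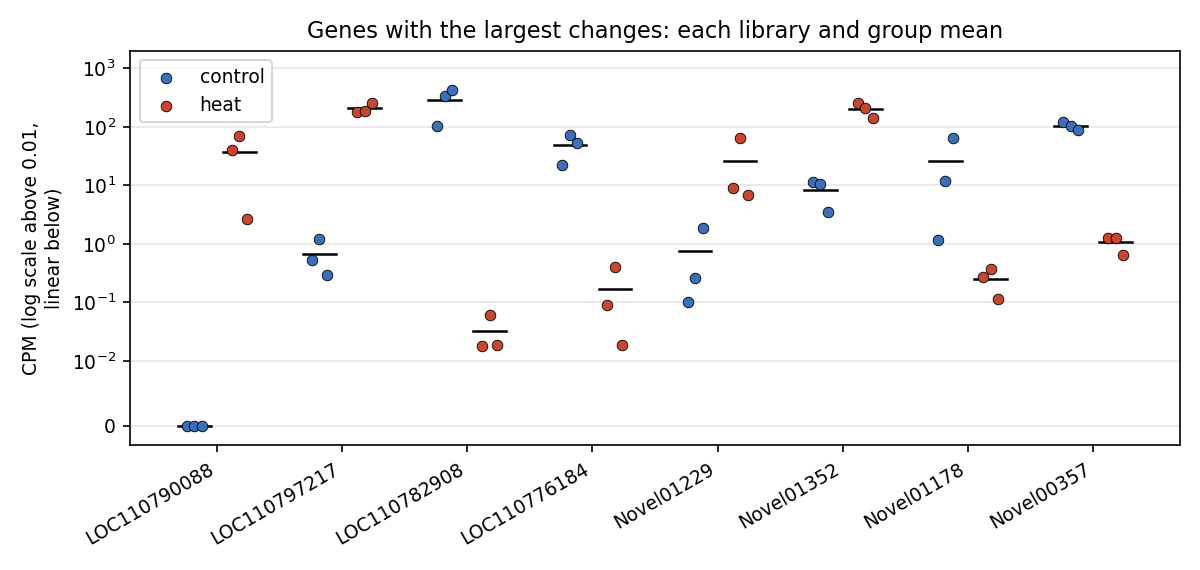
CPM on a log axis is plotted per library for the named genes and added gene models with the largest changes, with each point 1 library. LOC110797217 lies at 207 CPM on average in heat and 0.674 CPM in control.

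Gene models that the authors added to the annotation were called less often than annotated genes by edgeR's quasi-likelihood test. Of 1458 tested models, 275 (18.9%) passed, against 4799 of 18687 annotated genes (25.7%), with an odds ratio of 0.673 (95% interval 0.585 to 0.771; Fisher's exact test across genes, p = 3.02e-09). With DESeq2 this odds ratio was 0.993 (Fisher's exact p = 0.931). The tested models had a median of 2.00 CPM, against 16.3 CPM for protein-coding genes. Whether this lower level, at which changes are harder to detect, accounts for the fewer calls was not tested. Novel01352, on scaffold NW_018933625.1 from 2100 to 9210 on the minus strand, rose from 8.45 ± 4.36 to 202 ± 58.3 CPM (log2 fold change 4.58, SE 0.50, adjusted p = 0.00153). Novel00357, a model with 2 exons on scaffold NW_018931558.1 from 366905 to 369562 on the minus strand, fell from 105 ± 17.3 to 1.06 ± 0.348 CPM (log2 fold change -6.62, SE 0.32, adjusted p = 0.000277). Novel01229, on scaffold NW_018933131.1 from 124845 to 127167 on the minus strand, went from 0.751 ± 0.986 to 26.5 ± 32 CPM (log2 fold change 5.19, SE 1.33, adjusted p = 0.0298). Novel01178, on scaffold NW_018933032.1 from 202945 to 205341 on the plus strand, went from 25.7 ± 33.6 to 0.250 ± 0.128 CPM (log2 fold change -6.68, SE 1.48, adjusted p = 0.0180). The calls of these last 2 models were lost when single libraries were left out, Novel01229 without control library 1 or 2 or heat library 1 or 2 (adjusted p from 0.0523 to 0.101) and Novel01178 without any of the heat libraries (adjusted p from 0.0581 to 0.0763). Without control library 3 the log2 fold change of Novel01229 was 7.15 and that of Novel01178 -4.71, and without heat library 2 that of Novel01229 was 3.44. limma-voom also left both short of the threshold (adjusted p = 0.102 and 0.256). Coordinates are those of the authors' file, whose genome build is not given in the sources used here.

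The balance of higher and lower genes differed between classes of genes, although the side on which protein-coding genes leaned depended on the scaling. Among protein-coding genes 1848 were higher and 2471 lower, a share of 42.8% higher under TMM scaling, but under library size alone 5093 were higher and 1308 lower (79.6% higher), and on log2(FPKM + 1) 79.0% were higher. Long non-coding RNA (lncRNA) genes had 194 higher and 69 lower, or 73.8% higher (93.8% under library size alone), with an odds ratio of 3.76 against protein-coding genes (95% interval 2.82 to 5.06; Fisher's exact test across genes, p = 6.22e-23, adjusted p = 1.87e-22). The added models had 182 higher and 93 lower, or 66.2% higher (odds ratio 2.62, 95% interval 2.01 to 3.42; Fisher's exact p = 4.14e-14, adjusted p = 6.21e-14), and under library size alone 85.3% higher, with an odds ratio of 1.49. For unmatched genes 112 were higher and 96 lower (odds ratio 1.56, Fisher's exact p and adjusted p = 0.00201 over the 3 classes compared), and this did not pass under library size alone (odds ratio 1.2, p = 0.292) or without control library 2 or 3 or heat library 1 (odds ratio 1.31, 1.37 and 1.3).

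**Figure D4:**
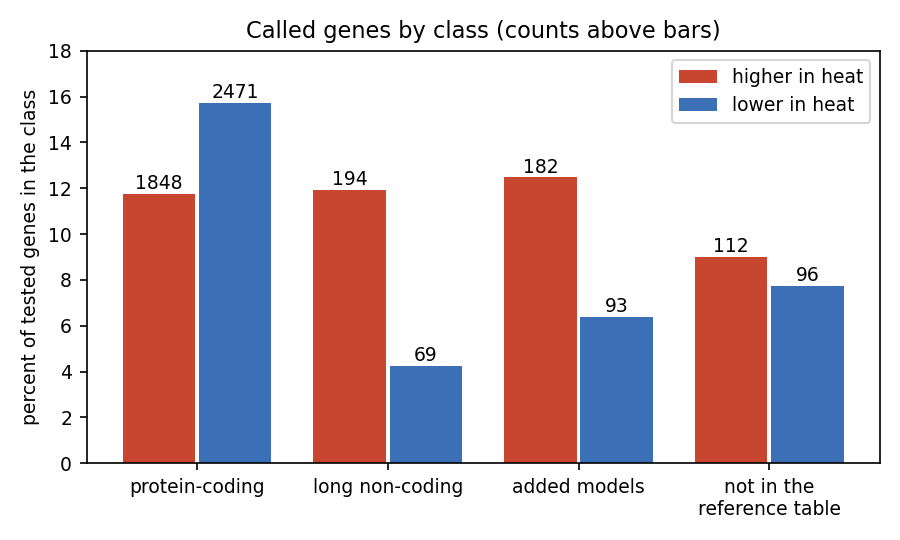
The percentages of tested genes higher and lower in heat under TMM scaling are plotted as bars for protein-coding, lncRNA, added and unmatched genes, with counts above. The lncRNA genes have 194 higher and 69 lower and the protein-coding genes 1848 higher and 2471 lower; under library size alone both have more higher than lower, 525 against 35 and 5093 against 1308.

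The most abundant transcripts were lower in heat. Of the 100 genes with the highest mean CPM, 62 fell, 8 rose and 30 did not pass, with a median log2 fold change of -1.41 (interquartile range -2.20 to -0.61). Their share of all counts went from 35.3% ± 2.03 in control to 20.9% ± 1.5 in heat (n = 3 each), and 18 of them had a reference name, of which 17 fell. Under library size alone, the median was -0.94. The most abundant gene, LOC110783009, which was chosen after its values were seen, went from 43860 ± 10466 to 15427 ± 4993 CPM (log2 fold change -1.51, SE 0.37, adjusted p = 0.0262), and its call was lost without control library 2 or 3 or heat library 1 or 3 (adjusted p from 0.0532 to 0.0927). In the 5145 least abundant tested genes, 461 were higher and 295 lower, and under library size alone 884 and 187.

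**Figure D5:**
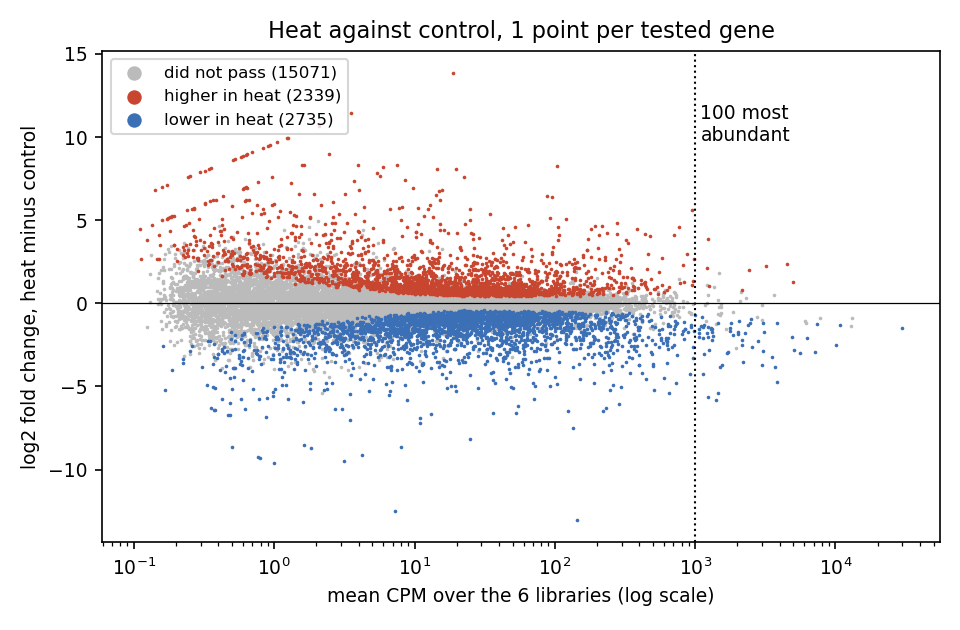
The log2 fold change (heat minus control) of each tested gene is plotted against its mean CPM on a log axis. The 100 most abundant genes have a median of -1.41, while the median of all 20145 tested genes is 0.01.

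In the reference table, 15 protein-coding genes carried a symbol other than a locus number, and the 5 that were tested are given here. NDK4, a nucleoside diphosphate kinase, fell from 78.0 ± 16.9 to 47.4 ± 7.34 CPM (log2 fold change -0.72, SE 0.20, adjusted p = 0.0391), a call lost without control library 1, 2 or 3 or heat library 1 or 3 (adjusted p from 0.0506 to 0.135) and under library size alone (log2 fold change -0.27). PSA, a phosphoserine aminotransferase, had 3.77 ± 0.716 CPM in control and 3.61 ± 1.02 CPM in heat (log2 fold change -0.06, adjusted p = 0.904; 0.42 under library size alone). Only 13 entries for plastid-encoded protein-coding genes were matched, and these had few reads, at most 214 in a library for petB. rbcL and psbA, which plastids also encode, were not among them, so plastid transcripts as a whole were not assessed. petB had 2.76 ± 2.54 CPM in control and 1.3 ± 0.206 CPM in heat (log2 fold change -1.08, adjusted p = 0.260; -0.007 without control library 3), atpF a log2 fold change of -1.77 (adjusted p = 0.119; -2.61 without heat library 1) and clpP one of 0.70 (adjusted p = 0.589; 1.52 without control library 3).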

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

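The gene groups and their alternatives, the thinned counts, the omission of the 100 most abundant genes, the directions of gene classes and the alternatives of the library measures were chosen after the data had been examined. The planned tests of the lists by description, with their alternatives, were not run because no descriptions were found. Of 1278 alternative values for 71 results, 1114 were judged the same as the main value. For tested results this meant the same direction and side of the threshold. For counts it meant a value within a fixed ratio of the main one, so DESeq2's 6657 changed genes counted as the same as 5074. For the median of the 100 most abundant genes and the library measures, it meant a distance below the pooled SD over libraries. Among settings chosen before the data were seen, 79 values no longer passed, 10 came to pass, 10 reversed and 37 moved in size, and among those chosen later 14, 3, 6 and 5 did. The cause was not tested for any change below unless it is given.

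Under library size alone, 7759 genes passed (6288 higher, 1471 lower), 3453 rose and 1128 fell at least 2-fold, and 3808 genes were shared with the TMM result. The odds ratio of unmatched genes was then 1.2, the median of the 100 most abundant genes -0.94, PSA at 0.42 and HEMB (LOC110796930) at 0.031. Adjusted p was 0.0294 for the ferredoxin-thioredoxin group, 0.0531 for plastid ribosomal proteins and 0.472, in the opposite direction, for antioxidant enzymes. limma on log2(FPKM + 1), where values are scaled by library totals alone, gave 6117 higher and 1459 lower genes, with 2351 and 918 at least 2-fold; with a pseudocount of 0.1 these were 6115, 1453, 3002 and 1047, and with no filter 6080, 1426, 2281 and 846. Their odds ratios of unmatched genes were 1.21, 1.16 and 1.08, the median of the 100 most abundant genes was -0.94 in each, and PSA stood at 0.26, 0.36 and 0.26 and HEMB at 0.017 in each. Without a filter, 41 of the 100 were lower and the odds ratio of added models was 0.904. On log2(FPKM + 1) with a minimum mean of 1, the ferredoxin-thioredoxin group reached an adjusted p of 0.0291 and antioxidant enzymes, reversed, 0.581. DESeq2 called 6657 genes and put the odds ratio of added models at 0.993. In the simulation 40.9% of its calls were unchanged genes, but far fewer genes were changed there. That share therefore does not carry over to the 6657 calls.

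With the replicate number as a block, 2628 genes passed (1048 higher, 1580 lower), 916 rose at least 2-fold, and the odds ratio of unmatched genes was 1.23. Deviations of libraries with the same number correlated at -0.13, -0.12 and -0.29, and no heat library correlated best with the control library of its own number, so the numbers gave no evidence of pairing. The block changed no call of a gene group. A threshold of 0.01 left 2032 genes (791 higher, 1241 lower), and a test against a 2-fold change, which asks more of each gene, 1152 (454 higher, 698 lower). With an estimated correlation, adjusted p was 0.127 for photosystem subunits, 0.173 for nitrogen assimilation, 0.164 for glycine betaine synthesis, 0.187 for HSP70 and 0.364 for plastid ribosomal proteins. The self-contained test fry, which does not set a group against other genes, left these groups past the threshold. Its adjusted p was 0.000222 for photosystem subunits, 0.00214 for nitrogen assimilation, glycine betaine synthesis and HSP70, and 0.0222 for plastid ribosomal proteins. The ferredoxin-thioredoxin group, which did not pass with camera, had 0.00397 with fry.

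Leaving out 1 library leaves fewer samples to test. The count of changed genes then ranged from 2291 (without control 2) to 4355, with 864 to 1924 higher and 1427 to 2464 lower. At least 2-fold, the total ranged from 2064 to 3331 and the higher genes from 763 to 1428. The odds ratio of unmatched genes ranged from 1.3 to 1.54, PSA from -0.19 to 0.16, and the adjusted p of antioxidant enzymes from 0.495 to 0.980 and of proteasome subunits from 0.602 to 0.966, with both directions seen. Thinning all libraries to the smallest total gave 5029 genes, so the difference in depth between the groups did not set the count. Of 13 matched entries for plastid-encoded protein-coding genes, 3 had enough reads to be tested, and why the others had few was not tested.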

Other observations

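The tests of scaling for the gene classes and the 100 most abundant genes, the tests of abundance for single photosynthesis groups, and all comparisons with other splits of the libraries, were chosen only after the results were seen, as were the gene groups themselves.

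The genes named for phosphoribosyl diphosphate synthase, which makes a precursor of nucleotides, did not move together. Beside the 18.2-fold rise of prs2 (LOC110792433), from 46.0 ± 16.9 to 837 ± 174 CPM, prs1 (LOC110793298) fell from 47.4 ± 2.72 to 32.3 ± 2.90 CPM (log2 fold change -0.55, SE 0.13, adjusted p = 0.0243) and prs3 (LOC110799228) from 6.89 ± 1.66 to 3.10 ± 0.624 CPM (log2 fold change -1.15, SE 0.29, adjusted p = 0.0287). prs4 (LOC110783966) had 56.6 ± 2.72 CPM in control and 75.1 ± 12.8 CPM in heat (log2 fold change 0.41, adjusted p = 0.105). These 4 genes were chosen after their values were seen, and edgeR's quasi-likelihood test was used. The calls of prs1 were lost without control 1, control 2, heat 1 or heat 3 (adjusted p from 0.0587 to 0.116) and those of prs3 without control 1, control 2, heat 1 or heat 2 (adjusted p from 0.0706 to 0.114). Under library size alone, prs1 (log2 fold change -0.10) and prs3 (log2 fold change -0.70) did not pass and prs4 did (log2 fold change 0.86, adjusted p = 0.00541).

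Of 29 tested genes placed in the photosynthesis groups, petB and atpF included, 27 fell, all nuclear, and 28 were lower adjusted over the list alone. The 27 had a median log2 fold change of -1.83 (-1.36 under library size alone; -1.81 over all 29), and the 100 most abundant genes as a whole were lower, with a median of -1.41. For the 27 nuclear genes the lowest median of 10000 random lists matched on mean CPM was -1.82. As low were 0% of the lists for these or for all 29, and 0.02% for the Calvin-Benson group. The lists were drawn gene by gene, whereas the estimated correlation was 0.36 between photosystem genes and -0.0009 between Calvin-Benson genes. They also left out every gene placed in a group, abundant ones that fell included. Within these limits, the values argue against high abundance alone mainly for the Calvin-Benson group. Lists as low made up 3.11% for the photosystem group and 3.2% for the 6 nuclear electron carriers. High abundance therefore stays open for both. With petB and atpF added, the share for the electron carriers was 0.97%. These 2 genes had at most 214 and 27 reads in a library, so that share is no test of high abundance. Scaling alone did not account for the fall of the 100 most abundant genes. Their median stayed at -0.94 under library size alone (bootstrap interval over genes, which are not independent, -1.21 to -0.72). Nor did short length account for it, since the lowest median of 10000 lists matched on length was -0.35. A coordinated decrease of Calvin-Benson transcripts under heat is a hypothesis that these values may allow, while tissue composition and the time of sampling, neither of which was tested, stay open.

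lncRNA genes and added models leaned higher in heat than protein-coding genes. Within deciles of mean CPM the odds ratio was 3.29 (95% interval 2.48 to 4.38) for lncRNA genes and 2.09 (1.60 to 2.72) for added models, which argues against expression level as the whole cause. Within deciles of length it was 3.97 (2.96 to 5.34) and 2.63 (2.03 to 3.41), and under library size alone 3.85 (2.72 to 5.62) and 1.49 (1.13 to 1.97). Neither length nor scaling therefore accounts for the lean as a whole. Strand was not tested, and reads from overlapping protein-coding genes could contribute.

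Neighbouring genes changed in the same direction more often than shuffled ones. In the gene order of the BTI_SOV_V1 table, 765 of 15700 pairs of tested protein-coding neighbours did so, against 608 (568 to 650) when calls were shuffled within deciles of mean CPM (one-sided permutation p = 1e-04, the smallest 10000 shuffles can give), so similar expression level does not account for it. Pairs whose lengths differ over 1.5-fold gave 352 against 336 (304 to 369; permutation p = 0.184), and pairs of similar length 413 against 272 (permutation p = 1e-04), and the ratios to the shuffled means differed by 0.475 (permutation p = 1e-04). The excess was thus found where neighbours may be similar copies, and reads shared between copies are a candidate explanation that the data could not separate from copies regulated alike. The longest run, of 7 genes from LOC110783250 to LOC110783252 and 827 to 991 bp in length, had log2 fold changes from -5.74 to -2.05 and was chosen after its values were seen.

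The 6 libraries form only 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 5074 changed genes, 3383 of them at least 2-fold, 275 added models, 194 lncRNA genes in one direction and 62 of the 100 most abundant genes in one direction, and the highest of the other splits gave 0 for each (1 of 10 splits as large in each case). The other splits mix both regimes on each side, so the difference between regimes widens the spread within their groups. Few calls were therefore likely in them, and the 0 is no measure of what chance alone would give. In those splits up to 1253 genes had an unadjusted p below 0.05 with edgeR, DESeq2 called up to 160 and limma-voom 0. For gene groups, the real split put 7 past the threshold and the highest other split 5. Every other split leaves unequal numbers of heat libraries on its sides, so part of the heat difference remains in it. These calls therefore cannot tell whether camera with its preset correlation calls groups falsely.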
